A study of Mus musculus with 5 samples.

How the data were processed

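The series holds 5 RNA-seq libraries of mouse male germ cells, 1 library for each of 5 stages. All 5 carry the genotype label Miwi+/-, that is, heterozygous for the gene now called Piwil1. RNA was taken with Trizol from testes or from cells sorted by flow cytometry, and the libraries were unstranded, per the labels. The submitters' processing notes name TopHat, Cufflinks and the mouse build mm9; versions, annotation and filters are not given in the sources used here.

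The authors deposited 1 table for the whole series. Each of its rows held an Ensembl gene ID, a gene symbol and 5 further columns of values, and the table had no header line. The 5 value columns therefore carried no names and 0 of them were matched to a sample. Columns were not assigned to stages by their order or by the values in them, because a wrong assignment would exchange stages without any sign of it. The 5 value columns were not used in any result, and the unit of their values is not stated in the sources used here. A first inspection of the table did look at column sums, ranges and correlations between the columns, and nothing from that inspection is reported.

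The comparisons planned before the data were examined (changes between consecutive stages, stage-restricted genes, and the level of preset gene lists in each stage) were not run, nor were the other settings planned for them for this reason. No expression level, fold change or test is given, and the depth of each library was not analysed here.

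Only the gene IDs and symbols were used. IDs were looked up, without version numbers, in the GENCODE M21 annotation (GRCm38), which is a later build than mm9. It was used for gene names, gene types and the chromosome of each gene, and no coordinates were taken from it. For each chromosome, the share of annotated protein-coding genes that the table lists was computed, with a 95% Wilson interval from scipy 1.17.1 under Python 3.11.15. These shares matched genes by ID alone, so a gene whose ID differed between annotations counted as not listed. The gene lists were matched by symbol as well, so their counts are not directly comparable with these shares. Each share is a complete count and not a random sample. The intervals therefore only describe the size of each gene set and cover no biological error. Members of 23 gene lists fixed before the data were examined were matched by symbol, by older symbol or by gene ID. A check of the matching on a small made-up table returned the known matches. It does not measure how well renamed genes are found in the deposited table. The named-gene rule fixed in advance needed expression values and was not applied. Genes are named here because they belong to a fixed list, and those singled out were chosen after it was seen whether the table lists them. Whether a gene is listed is a property of the deposited table, and it is not a measurement of expression in any stage.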

Results

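The study sequenced RNA from mouse spermatogenic cells at 5 stages. There were 4 stages of spermatocytes (leptotene with zygotene, then early, middle and late pachytene, the last together with diplotene), followed by round spermatids. Leptotene to diplotene are the successive stages of meiotic prophase, in which homologous chromosomes pair and recombine, and round spermatids are the haploid cells that follow the meiotic divisions. Each stage was represented by 1 library, so no stage had a replicate. The design asks how the transcriptome changes from one stage to the next. Those comparisons were not analysed here, because the 5 value columns of the deposited table have no names and could not be matched to stages. What follows describes which genes the table lists.

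The table listed 13595 genes, each with its own Ensembl ID, and 31 symbols stood on more than 1 row. Of these IDs, 13396 (98.54%) were found in GENCODE M21 and 199 were not. On 11789 rows the symbol was the same as in that annotation. Among those found, 98.18% were protein-coding genes. Processed pseudogenes made up 0.49% and long intergenic non-coding RNAs 0.43%.

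The table listed 12632 of the 20807 annotated autosomal protein-coding genes, or 60.7% (95% Wilson interval 60.0 to 61.4%). On the X chromosome it listed 506 of 948, or 53.4% (50.2 to 56.5%). The autosomes ranged from 50.4% on chromosome 14 to 70.6% on chromosome 12, and 3 autosomes lay below the X. Without the chemosensory receptor genes, 1 autosome lay below the X, chromosome 14 at 52.7% against 53.9%. Genes named Gm or Rik carry symbols of a type given to predicted models and clones, although the annotation counts these genes as protein-coding. Without them, 2 autosomes lay below the X, the lowest being chromosome 7 at 53.5% against 57.2%. On the Y chromosome 7 of 183 protein-coding genes were listed, or 3.83% (1.87 to 7.68%). Without genes named Gm or Rik it was 7 of 17, or 41.2%. The higher share came from the smaller gene set, since the count listed stayed at 7. The 183 are those of the later annotation, and it was not checked how many of them the mm9 processing could have listed. Of the mitochondrial genome's 13 protein-coding genes, 7 were listed. Olfactory, vomeronasal and trace amine receptors, which are chemosensory genes, together had 12 of 1481 members in the table.

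For meiotic recombination, 34 of 35 members were listed, among them Spo11, which makes the programmed double-strand breaks, Dmc1, the meiotic strand-exchange protein, and Prdm9, which sets the position of hotspots. For the synaptonemal complex and chromosome axis, 18 of 19 were listed, including Sycp1, Sycp2 and Sycp3. The piRNA pathway had 25 of 27 members in the table, among them Piwil1, the gene of the genotype label, Piwil2 and Mov10l1. The list of the G2/M transition and meiotic divisions had 33 of 34. Spermatogonial and preleptotene genes had 21 of 22, among them Kit and Stra8, and DNA replication genes had 30 of 32. Some lists not drawn up for germ cells were also largely complete, with 94.59% for the proteasome and 88.89% for ubiquitously expressed X-linked genes. High shares were therefore not particular to germ cell lists. Somatic cell markers and DNA methylation genes, given below, had lower shares. The share of autosomal protein-coding genes, counted by ID alone, was 60.71%.

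For haploid functions, all 22 members of the list for nuclear condensation in spermatids were in the table. They include the transition protein genes Tnp1 and Tnp2 and the protamine genes Prm1 and Prm2, whose products replace histones. That list also holds Rnf8, which is a member of the DNA damage list as well. The acrosome list had 37 of 40 members, among them Acr, the acrosin gene, and Izumo1, which acts in gamete fusion. The flagellum list had 47 of 49, including Odf1 and Akap4. All 24 members of the list drawn up for regulators of late meiotic and haploid cells were in the table. Among them were the transcription factor genes Crem and Rfx2, but also Zmynd10 and Meioc, which are not known as transcription factors. All 33 members of the list of testis metabolic enzymes and sperm energy supply, such as Ldhc and Gapdhs, were in the table. That list also holds enzymes that are not testis forms, such as Tpi1, Gpi1 and Hk1. Germ cell RNA-binding and translational control genes had 35 of 36 members with a known symbol. Outside haploid functions, the list for the DNA damage response at unsynapsed chromatin had 32 of 35 and that for the proteasome 35 of 37.

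For the X chromosome, 48 of the 54 members of the list of ubiquitously expressed X-linked genes were in the table. The 6 not found in it were Pgk1, which encodes a glycolytic enzyme, Eif2s3x, Rps4x, Med12, Hmgb3 and Naa10. All 13 members of the list of autosomal testis genes with an X-linked parental gene were in the table, including Pgk2, Pdha2 and Cetn1. The X-linked genes Pdha1, Cetn2, G6pdx and Rbmx were in the table too. Of the Y-linked list, 7 of 13 genes were in the table, including Zfy1, Zfy2 and Ddx3y; the 6 others included the multicopy genes Ssty1, Ssty2 and Sly.

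Of the markers of testicular somatic cells, the table held 15 of 20 Sertoli cell markers, 12 of 16 Leydig cell markers, 13 of 16 peritubular markers and 15 of 22 macrophage, endothelial and blood markers with a known symbol. These shares were 75.0, 75.0, 81.25 and 68.18%, against 60.71% of autosomal protein-coding genes, which were counted by ID alone. Their Wilson intervals were 53.13 to 88.81, 50.5 to 89.82, 56.99 to 93.41 and 47.32 to 83.64%, and each includes 60.71%. Most other lists had higher shares, such as 89.33% for ribosomal proteins and 93.75% for DNA replication. The DNA methylation list had 76.19% and the Y-linked list 53.85%. From the Sertoli list Wt1, Clu, Gata4, Cldn11 and Inha were in the table, while Sox9, Amh and Fshr were not found in it. The DNA methylation list had 16 of 21 members; Dnmt1 and Dnmt3a were listed and Dnmt3b, Dnmt3l and Tet1 were not found. Of the cytosolic ribosomal proteins, 67 of 75 were listed. These are counts of listed genes without a test, and they carry no information on the stage in which a gene was measured.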

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

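All alternatives given here were chosen after the data were seen; none of the planned ones was run, since each needs expression values matched to stages. Without the chemosensory receptor genes, the share of autosomal protein-coding genes listed was 65.27% and that of the X was within its interval. Without protein-coding genes named Gm or Rik, the share was 63.94% for autosomes, 57.2% for the X and 41.18% for the Y. Only 17 Y genes then remained in the annotation. The autosomal values, and the X and Y values without genes named Gm or Rik, lay outside the intervals of the main shares. Of 695 list members with a known symbol, counted once per list, 632 were listed; matching by the table's symbols alone gave 613 and leaving out older symbols gave 627. None of these list counts moved by more than 1.5 times in any of the 23 lists. For leaving out older symbols this was a weak check, since few list members had one. How the values themselves depend on scaling, pseudocount or filters was not tested. No library depth was analysed here.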
